A study of Mus musculus with 6 samples.

How the data were processed

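Messenger RNA was measured in 6 libraries of mouse ES cells, 3 labelled as expressing 3XHA-Taf13 without treatment and 3 labelled KO with doxycycline. Per the labels' protocols, libraries were made from 800 ng of total RNA with a stranded poly(A) kit that marks strand with dUTP, and were amplified with 12 PCR cycles. The labels name separate Petri dishes for the replicates of each condition, so the spread between libraries includes the spread between dishes, though the dishes may share a starting culture. Each group was taken from the sample titles and the treatment label.

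The deposited table holds whole-number read counts per gene, not normalized, for 55401 Ensembl gene identifiers in 6 library columns. Per the submitters' processing notes, bcl2fastq 2.20.0.422, cutadapt 1.10, STAR 2.5.3a and HTSeq 0.6.1p1 were used with the mouse build mm10. Their settings, the strand option of the counting step and the annotation release are not given in the sources used here. Reads of a gene and of an overlapping gene on the opposite strand therefore may not be fully separated, and reads that map equally well to several copies may have been dropped or split. Of the 152 genes chosen by the rule given below, 39 overlap an annotated gene on the opposite strand (Cubn, Sox17, Habp2, Corin, Pck2, Napsa, Taf5, Taf4, Taf6, Tbp, Taf11, Taf3, Taf10 and Pou5f1 among them) and 12 on the same strand (Klhl13, Pdgfra, Taf9, Rps3, Rps12 and Rpl3 among them), and their values are uncertain to that extent. Symbols, positions and gene classes were taken by identifier from a GENCODE annotation of the same build, which named 55141 of the 55401 identifiers. Identifiers without a symbol held at most 0.00465% of the counts of a library.

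Total counts ran from 31219328 to 50328010 per library. A count of 3 corresponds to 0.0581 to 0.0961 CPM, and such floors and counting intervals cover counting error only, since PCR copies were not told apart. The number of genes with a count in any library was 33589. The 3 pairs within each group differed by more than sampling noise (chi-square per degree of freedom from 3.52 to 38.4), so no library was counted as a copy of another. Expressing replicate 1 stood apart: its pairs with the other expressing libraries gave 38.4 and 31, against at most 6.35 for the remaining pairs, its deviation from the group mean correlated with GC content across genes (r = 0.558, across genes, which are not independent replicates), and its read-weighted GC content was 48.5% against 47.7% and 47.8%. It was kept. The first principal component of log2 CPM held 67.3% of the variance and separated the groups, and the second held 14.2% and separated expressing replicate 1 (34.6) from expressing replicates 2 (-21.3) and 3 (-17.2). No sequencing batch or date is given in the sources used here.

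Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), which left 17778, libraries were scaled by TMM, and a negative binomial model with the group as its only term was fitted with glmQLFit (robust) and tested with glmQLFTest. P-values were adjusted over all tested genes by the Benjamini-Hochberg method, with a threshold of 0.05, and adjusted p-values of single genes come from this edgeR test unless another fit or tool is named. The common biological coefficient of variation was 9.05%. Standard errors and 95% intervals were derived from the test statistic and its degrees of freedom. A gene counted as bounded within 2-fold when its 95% interval lay between a log2 fold change of -1 and 1. CPM values use the TMM-scaled library sizes.

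A test on simulated data used the same 17778 genes and library sizes, with 200 genes changed by known folds and a further small set raised slightly. The edgeR step recovered 41.8% of genes changed 1.5-fold, 77.6% of those changed 2-fold and 100% of those changed 4-fold. It called 14 unchanged genes, and its 95% intervals held the true value for 95.2% of genes. The share of unchanged genes among all its calls is not given here, so these 14 do not show that the share stayed under 0.05. Far fewer genes changed in the simulation than were called in the data. The adjusted threshold was therefore stricter there, and the recovered shares do not estimate recovery in these data.

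Before the data were examined, 30 gene lists, the tests and the rule for named genes were fixed. The lists were TFIID subunits, SAGA and ATAC coactivators, general transcription factors with RNA polymerase II subunits, Mediator, pluripotency, formative and primed state, primitive endoderm, trophectoderm, primitive streak and mesoderm, neural, fibroblast, 2-cell-like state, germline, p53 targets, integrated stress response, endoplasmic reticulum unfolded protein response, heat shock, mitochondrially encoded, oxidative phosphorylation, glycolysis and hypoxia, cholesterol synthesis, ribosomal proteins, S phase, G2 and M phase, immediate-early, FGF and ERK, WNT, TGF-beta, imprinted and interferon-stimulated genes. They were tested with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry, each adjusted over the 30 lists. Of the list genes, 43 were not among the tested genes. Named genes are Taf13 and the TFIID list, the 12 largest log2 fold changes in each direction among called genes of at least 1 CPM whose groups do not overlap, the 4 smallest adjusted p-values in each direction, up to 4 called members of each list with the smallest adjusted p, and Pou5f1, Sox2 and Nanog. Some genes that this rule picks are not reported here. Library measures were compared with an exact two-sided permutation test.

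The alternatives fixed before the data were examined were DESeq2 size factors, library totals without TMM, no filter on low counts, a filter of at least 1 CPM in 3 libraries, the DESeq2 1.42.0 Wald test, the replicate number as a block, genes with symbols of predicted genes (Gm and digits, or ending in Rik or in -ps and a number) left out, which keeps some annotated pseudogenes, an estimated correlation or fry for the lists, and each library left out in turn. Removing a trend with GC content from each library was added after seeing the data. No sample was left out of the main comparison. Splice variants and unspliced reads were not analysed here, since the table holds one count per gene.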

Results

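Polyadenylated RNA was sequenced from mouse embryonic stem (ES) cells, the cultured pluripotent cells derived from the early embryo. The series asks how messenger RNA levels respond to the loss of TAF13, a subunit of TFIID, the complex that helps recruit RNA polymerase II to promoters. Of the 6 libraries, 3 are labelled as cells expressing a 3XHA-tagged Taf13 and received no treatment, and 3 are labelled KO and received doxycycline. Cells were cultured for 7 days with or without the drug, and each library came from a separate Petri dish. Doxycycline and the KO label always go together here, so each difference below is one between dishes with both and dishes with neither. The total count per library was 31219328, 45957003 and 38561980 in the expressing libraries and 33953189, 43346441 and 50328010 in the libraries labelled KO. Levels are in CPM, gene counts scaled to library size, as mean ± SD of 3 libraries, and fold changes are log2, the libraries labelled KO minus the expressing libraries, with their standard error (SE).

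Taf13 itself (ENSMUSG00000048100; chromosome 3, 108571698 to 108583222, mm10) was not lower in the libraries labelled KO. Its counts were 244, 445 and 447 in the expressing libraries and 422, 634 and 699 in the libraries labelled KO, or 10.05 ± 2.21 CPM (SD, n = 3) against 13.24 ± 1.02 CPM (SD, n = 3). The log2 fold change was 0.40 (SE 0.147), with an adjusted p of 0.0578 in edgeR's quasi-likelihood test, and the 95% interval ran from 0.06 to 0.73. Without expressing replicate 1 the log2 fold change was 0.28 and without expressing replicate 3 it was 0.57, both with adjusted p below the threshold (0.0126 and 0.0151, edgeR). It did not pass without expressing replicate 2 (adjusted p = 0.1, edgeR), KO replicate 1 (0.0789), KO replicate 2 (0.166) or KO replicate 3 (0.15). The counts do not tell reads of the tagged Taf13 from reads of the chromosomal gene, so the targeted gene does not check the labels, and the directions below rest on the labels alone.

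Among the 17 TFIID subunit genes tested, 3 rose and 4 fell in the libraries labelled KO, and the same counts were obtained with p adjusted over the list alone (edgeR). Taf7l, the germ-cell paralogue of Taf7, rose from 10.11 ± 0.91 to 18.05 ± 1.15 CPM (SD, n = 3; log2 fold change 0.83, SE 0.0965, adjusted p = 1.68e-04, edgeR). Taf9b (0.51, SE 0.129) and Taf12 (0.30, SE 0.0638) also rose. Taf5, the WD40-repeat scaffold subunit, fell from 42.5 ± 2.66 to 25.9 ± 0.569 CPM (-0.71, SE 0.0722, adjusted p = 7.83e-05, edgeR), followed by Taf8 (-0.63, SE 0.0705), Taf7 (-0.36, SE 0.0634) and Taf1, the largest subunit (-0.22, SE 0.0543). The remaining 10 members, Taf13 included, did not pass the test; Tbp, the TATA-binding protein gene, had a log2 fold change of -0.08 (SE 0.0714) and Taf11, whose product pairs with TAF13, -0.04 (SE 0.0608). As a group the subunits had a median log2 fold change of -0.01 and did not stand apart from other genes (camera, adjusted p = 0.85). Taf9 was counted at only 0.768 ± 0.171 and 0.674 ± 0.0733 CPM and shares its locus with Ak6 on the same strand, so its value is uncertain.

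Several TFIID calls moved when a library was left out. The Taf1 call was lost without expressing replicate 3 (adjusted p = 0.0506, edgeR), KO replicate 1 (0.0528) or KO replicate 2 (0.0539), and the Taf9b call without KO replicate 3 (0.0576). Without expressing replicate 1, Taf4 (0.0466), Taf4b (0.00666), Taf6 (8e-05) and Tbp (0.0271) passed as well, which with Taf13 made 6 higher and 6 lower. With libraries scaled by their totals alone, the Taf1 call was lost (adjusted p = 0.0587, edgeR) and Taf13 (0.0197), Taf4 (0.0337) and Taf2 (0.0223) passed, for 6 higher and 3 lower, and with the GC trend removed 5 were higher and 6 lower.

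**Figure D1:**
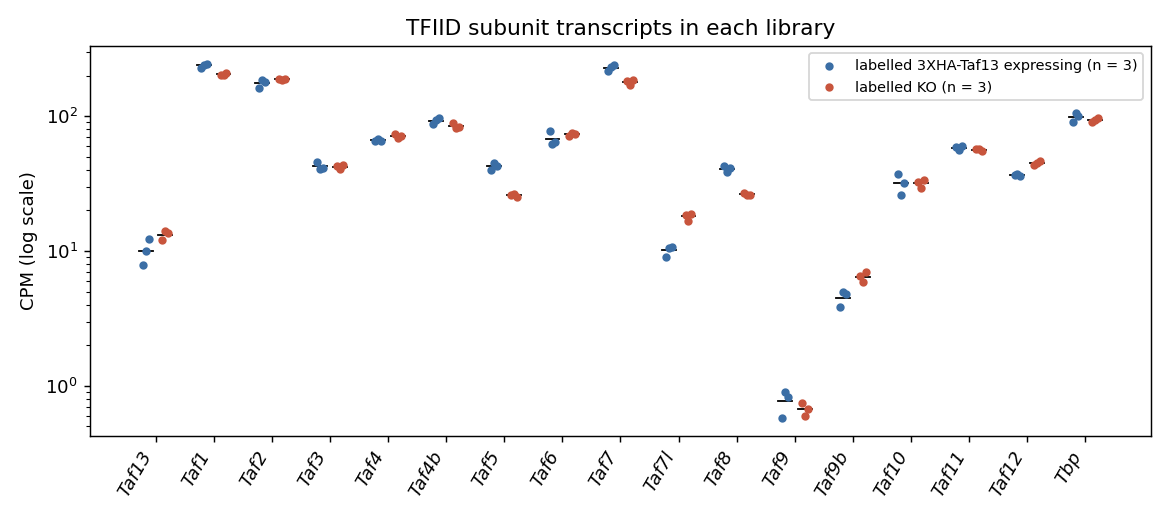
CPM of Taf13 and the other tested TFIID subunit genes in each of the 6 libraries, on a log axis. Points are libraries and black bars are group means (n = 3). Taf13 averaged 10.05 CPM in the expressing libraries and 13.24 CPM in those labelled KO, while Taf5 and Taf8 fell and Taf7l rose.

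Of 31 genes for general transcription factors and RNA polymerase II subunits, 2 rose and 12 fell (2 and 12 adjusted over the list alone). Polr2a, the largest RNA polymerase II subunit, rose by 0.56 (SE 0.0801) from 662 ± 78.7 to 978 ± 23.9 CPM, and Gtf2a1, named after its value was seen, rose by 0.50. Polr2i (-0.70, SE 0.0819), Polr2h (-0.36, SE 0.0683) and Gtf2h3 (-0.33, SE 0.0596) fell. Of 31 Mediator genes, 7 fell and 0 rose (3 and 0 adjusted over the list alone) in edgeR, with Med28 at -0.45 (SE 0.0643), and 0 were higher at an unadjusted p under 0.05 or by DESeq2. Of 25 SAGA and ATAC coactivator genes, 3 rose and 9 fell (the same adjusted over the list alone), among them Kat2b, a histone acetyltransferase (-0.61, SE 0.0742), and Taf5l (-0.42, SE 0.0563). None of these 3 lists differed from other genes by camera (adjusted p = 0.078 for the general factors, 0.092 for Mediator and 0.12 for SAGA and ATAC). The general factors did with the GC trend removed (0.026), while with an estimated correlation and no such removal their adjusted p was 0.25. By fry, which does not compare a list with other genes, all 3 lists were lower (adjusted p = 0.0042, 0.00057 and 2e-04). The 12 decreases among the general factors became 6 without expressing replicate 3, 5 without KO replicate 1, and 4 without KO replicate 2, without KO replicate 3 or with library totals, and the SAGA and ATAC counts became 3 higher and 5 lower with library totals. Mediator genes numbered 3 higher and 11 lower without expressing replicate 1, 0 and 3 without expressing replicate 3, KO replicate 1 or KO replicate 3, 0 and 4 without KO replicate 2 or by DESeq2, 4 and 13 with the GC trend removed, and 4 and 3 with library totals. The counts of this list thus turned with the scaling. Library totals moved the median of all genes from -0.01 to 0.08 as well, and the Mediator median stayed below 0 (-0.14 in the reported fit, -0.05 with library totals).

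Across the genome, 3422 of 17778 tested genes were higher and 3695 lower in the libraries labelled KO (edgeR, Benjamini-Hochberg adjusted p under 0.05), which is 19.2% and 20.8% of them. Most changes were small, with a median absolute log2 fold change of 0.557 among the called genes. At 2-fold or more, 928 genes rose and 647 fell. For 12987 genes (73.1%) the 95% interval lay within 2-fold in either direction, and 4436 of these were also called. A further 2110 genes were neither called nor bounded in this way. Library groups did not overlap for 53.5% of the tested genes, against 10% by chance. The median log2 fold change of all tested genes was -0.01. With libraries scaled by their totals alone, 4466 genes were higher and 2570 lower, so that 63.5% of the called genes were higher against 48.1% with the scaling used here. Equal amounts of total RNA went into each library and no spike-in was used here, so a shift of all messenger RNA per cell would not appear in these values. With only genes of at least 1 CPM in 3 libraries, 565 rose and 387 fell by 2-fold or more.

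**Figure D2:**
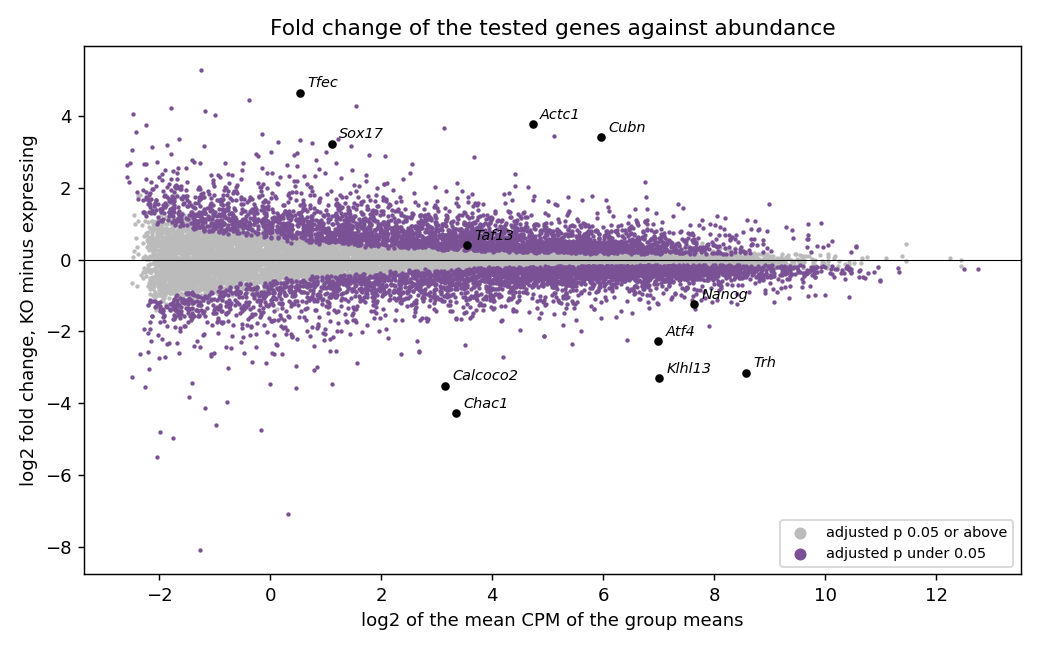
Log2 fold change (libraries labelled KO minus expressing libraries) against the log2 of the mean CPM for the 17778 tested genes. Each point is a gene, in purple where it passed the test in edgeR (7117 genes), and named genes are in black. Most coloured points lie close to 0, with a median absolute log2 fold change of 0.557.

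Cubn, which encodes the endocytic receptor cubilin (chromosome 2, 13276338 to 13491813), rose from 10.73 ± 0.558 to 114.2 ± 5.86 CPM (SD, n = 3; log2 fold change 3.41, SE 0.0755, adjusted p = 4.52e-08, edgeR). Tfec, a transcription factor of the MiT family, rose by 4.65 (SE 0.311), Nostrin by 4.27 (SE 0.185), and Actc1, cardiac actin, by 3.78 (SE 0.136) from 3.64 to 49.5 CPM. Srgn (3.65), AI481877 (3.45), Klb, the co-receptor for endocrine FGFs (3.36), Habp2 (3.34), Corin (3.28), Minar2 (3.23), Sox17 (3.23) and Tnfaip6 (3.18) complete the 12 largest increases among genes of at least 1 CPM. Car4 (1.78, SE 0.0643) and Scn3b (2.04, SE 0.0759), an auxiliary sodium channel subunit, were among the 4 increases with the smallest p.

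Klhl13, an adaptor of a CUL3 ubiquitin ligase (chromosome X, 23219271 to 23365082), fell from 234.0 ± 24.0 to 23.8 ± 1.69 CPM (SD, n = 3; log2 fold change -3.29, SE 0.0939, adjusted p = 1.79e-07, edgeR). Trh, which encodes the precursor of thyrotropin-releasing hormone, fell from 685 ± 81 to 77.5 ± 5.99 CPM (-3.15, SE 0.0976). Chac1, a glutathione-degrading enzyme, had a log2 fold change of -4.28 (SE 0.174), Pramel7 -3.58 (SE 0.245), Calcoco2, an autophagy receptor, -3.51 (SE 0.130), Napsa -2.99, Nlrp4a -2.89 and Pck2, mitochondrial phosphoenolpyruvate carboxykinase, -2.72. Atf4 (-2.27, SE 0.0655) and Rpl39l (-2.13, SE 0.0701) had 2 of the 4 smallest p-values among the decreases. Gm9643, a processed pseudogene, had 275 counts over the expressing libraries and 2 over the libraries labelled KO, 162 times fewer after scaling (95% counting interval 44.4 to 1340). The other predicted genes or unnamed transcripts among the 12 largest decreases were Gm10522, Gm40977 and 2310043M15Rik.

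Markers of primitive endoderm, the extraembryonic lineage that forms beside the epiblast in the blastocyst, rose together. Of 20 tested members 19 rose and 0 fell in edgeR (0 fell at an unadjusted p under 0.05 and by DESeq2), and the counts adjusted over the list alone were identical. The median log2 fold change was 1.96. Besides Cubn and Srgn, Pdgfra rose by 2.87 (SE 0.108) from 3.09 ± 0.347 to 22.6 ± 1.34 CPM (SD, n = 3), and Lama1, a basement membrane laminin chain, by 2.15 (SE 0.0895) from 39.5 ± 4.79 to 175.4 ± 6.75 CPM. Only Fst, named after its value was seen, did not pass (0.15, SE 0.107). The list stood apart from other genes by camera with a preset correlation (adjusted p = 3.5e-13), but not when the correlation was estimated (adjusted p = 0.14 with an estimated correlation).

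Pluripotency genes fell. Of 26 tested members 22 fell and 1 rose (24 and 1 adjusted over the list alone), with a median log2 fold change of -0.68 (camera, adjusted p = 6.3e-10, and adjusted p = 0.14 with an estimated correlation). Nanog fell from 281.2 ± 21.8 to 118.7 ± 6.75 CPM (SD, n = 3; log2 fold change -1.24, SE 0.0735), Pou5f1, which encodes OCT4, from 828 ± 124 to 498.3 ± 10.01 CPM (-0.73, SE 0.0947), and Sox2 from 279 ± 65.6 to 189.5 ± 5.89 CPM (-0.56, SE 0.144, adjusted p = 0.013, edgeR). The Sox2 call was lost without expressing replicate 2 (adjusted p = 0.0706, edgeR) and without KO replicate 2 (0.0542). The 4 members with the smallest p were Zfp42 (-1.37, SE 0.0584), Prdm14 (-2.58, SE 0.12), Tcl1 (-1.68, SE 0.0880) and Nr0b1 (-1.53, SE 0.0842). Gdf3, the member that rose, was named after its value was seen (0.40), as was Lin28a, which did not pass (0.01, SE 0.0564). Genes of the formative and primed states, which follow the naive state in development, also mostly fell: 10 of 17 fell and 2 rose (the same adjusted over the list alone), with Dnmt3b, a de novo DNA methyltransferase, at -1.07 (SE 0.0555), Fgf15 at -1.43 (SE 0.0848), Zic2 at -0.94 (SE 0.0677) and Foxd3 at -1.10 (SE 0.0902). Their median was -0.41 (camera, adjusted p = 0.015, and adjusted p = 0.3 with an estimated correlation), and the camera call was also lost with the GC trend removed (adjusted p = 0.095). Without expressing replicate 1, 4 were higher and 10 lower, and with the GC trend removed 4 and 9.

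Markers of other lineages went both ways. Trophectoderm markers numbered 4 higher and 7 lower of 18 (5 and 8 adjusted over the list alone), with Gata3 at 1.43 (SE 0.159) and Cdx2 at -1.05 (SE 0.114). Primitive streak and mesoderm markers numbered 4 higher and 2 lower of 15 (the same adjusted over the list alone): Kdr, the VEGF receptor 2 gene, rose by 2.03 (SE 0.114), while T, brachyury, fell (-1.19, SE 0.0957). Those streak counts were 5 higher and 1 lower without expressing replicate 1 or KO replicate 1, 3 and 1 without KO replicate 3, by DESeq2 or with genes of at least 1 CPM, 7 and 2 with the GC trend removed, and 7 and 3 without a filter. Neural markers numbered 5 higher and 7 lower of 17 (5 and 8 adjusted over the list alone), with Sox1 at 1.5 (SE 0.144) and the neurofilament gene Nefl at -0.73 (SE 0.0680), and their median was -0.19 while their mean was 0.11. None of these 3 lists passed camera (adjusted p = 0.76, 0.48 and 0.48). Germline genes numbered 8 higher and 5 lower of 28 (the same adjusted over the list alone; camera, adjusted p = 0.57), with Tex11 at 1.12 (SE 0.123) and Prdm1 at -1.46 (SE 0.146), and 9 higher and 8 lower with the GC trend removed.

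Genes of the 2-cell-like state, a rare state of ES cells resembling the cleavage-stage embryo, rose. Of 21 tested members 17 rose and 0 fell in edgeR, the same adjusted over the list alone (0 fell at an unadjusted p under 0.05 and by DESeq2), with a median log2 fold change of 0.92 (camera, adjusted p = 2.4e-07, and adjusted p = 0.25 with an estimated correlation). Zfp750 rose by 1.53 (SE 0.102) from 6.81 to 19.6 CPM, Gm12794 by 1.68 (SE 0.135), Usp17la by 1.64 (SE 0.128) and Usp17lb by 1.58 (SE 0.132). The Usp17l and Zscan4 families are near-identical copies whose reads counting can split, so their individual values are uncertain. Imprinted genes numbered 12 higher and 7 lower of 32 (15 and 7 adjusted over the list alone), with Sgce at 1.75 (SE 0.0973), Mest at 0.96 (SE 0.0648), Ndn at 0.90 (SE 0.0700) and Magel2 at -1.43 (SE 0.114). Their camera result (adjusted p = 0.049, and adjusted p = 0.23 with an estimated correlation) was lost without expressing replicate 1 (0.068), 2 (0.056) or 3 (0.052), without KO replicate 2 (0.07) or 3 (0.057), with DESeq2 size factors (0.051) and with the GC trend removed (0.07).

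Fibroblast markers, listed because ES cells are often grown on feeder fibroblasts, numbered 12 higher and 1 lower of 24 (the same adjusted over the list alone). The increases included the actin-cytoskeleton and matricellular genes Acta2 (1.55, SE 0.171), Ccn1 (1.43, SE 0.0620), Ccn2 (1.11, SE 0.0902) and Tagln (0.96, SE 0.105), which many cell types express. The abundant fibroblast collagens, named after their values were seen, did not pass: Col1a1 was at 49.6 ± 8.62 and 52.3 ± 20.5 CPM (SD, n = 3; log2 fold change 0.08, SE 0.237), Col1a2 had a log2 fold change of 0.15 (SE 0.267) and Col3a1 of 0.17 (SE 0.177). Col1a1 stood at 76.0 CPM in KO replicate 2 against 40.9 and 40.1 CPM in the other libraries labelled KO. The list passed camera (adjusted p = 0.015, and adjusted p = 0.67 with an estimated correlation; fry, adjusted p = 0.059), but without KO replicate 2 it did not (adjusted p = 0.16), and 9 members were then higher and 3 lower.

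Targets of the integrated stress response, the programme run by the transcription factors ATF4 and CHOP that raises amino acid synthesis, fell. Of 28 tested members 22 fell and 3 rose, the same adjusted over the list alone, with a median log2 fold change of -1.02 (camera, adjusted p = 1e-08, and adjusted p = 0.14 with an estimated correlation). Atf4 fell from 210.7 ± 8.94 to 43.6 ± 2.21 CPM (SD, n = 3; -2.27, SE 0.0655), Mthfd2, a mitochondrial folate enzyme, from 113.0 ± 6.10 to 37.2 ± 1.42 CPM (-1.60, SE 0.0667), Pck2 from 31.9 ± 3.83 to 4.82 ± 0.121 CPM, and Chac1 from 19.5 ± 1.99 to 0.988 ± 0.290 CPM. Ddit4 (0.80), Ppp1r15a (0.31) and Atf3 (0.38) were the members that rose, and Asns, asparagine synthetase, was at 263.2 ± 5.65 and 242.4 ± 10.8 CPM (-0.12, SE 0.0560) without passing the test; these 4 were named after their values were seen. Without KO replicate 1, 1 member was higher and 22 lower, and with the GC trend removed 5 and 23.

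Targets of p53, the tumour suppressor that responds to DNA damage, rose. Of 30 tested members 23 rose and 2 fell, the same adjusted over the list alone, with a median log2 fold change of 0.62 (camera, adjusted p = 1.1e-07, and adjusted p = 0.14 with an estimated correlation). Cdkn1a, the cyclin-dependent kinase inhibitor p21, rose from 70.6 ± 2.88 to 146.3 ± 9.23 CPM (SD, n = 3; 1.05, SE 0.0668), Plk2 from 159.2 ± 3.46 to 369.7 ± 13.8 CPM (1.22, SE 0.0553), Btg2 by 1.05 (SE 0.0574) and Cd80 by 1.85 (SE 0.103). Sesn1 (-0.45) and Gdf15 (-1.79), named after their values were seen, fell, and Bax, a pro-apoptotic member, did not pass (-0.17, SE 0.0984). With genes of at least 1 CPM alone, 23 members were higher and 1 lower.

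Of the other stress lists, immediate-early genes numbered 10 higher and 3 lower of 22 (the same adjusted over the list alone), with Fosl1 at 1.1 (SE 0.127), Fosl2 at 0.97 (SE 0.0772) and Fos at 0.86 (SE 0.0966). Their camera result (adjusted p = 0.046, and adjusted p = 0.45 with an estimated correlation) was lost without expressing replicate 2 (0.12), expressing replicate 3 (0.062) or KO replicate 2 (0.057). Genes of the endoplasmic reticulum unfolded protein response numbered 3 higher and 3 lower of 20 (the same adjusted over the list alone; camera, adjusted p = 0.62), with Herpud1, also an ATF4 target, at -1.28 (SE 0.0892); their median was 0.10 and their mean -0.02. Without expressing replicate 1 that list had 12 higher and 3 lower, with library totals 9 and 3, and with the GC trend removed 9 and 5. Heat shock genes numbered 2 higher and 8 lower of 18 (2 and 9 adjusted over the list alone; camera, adjusted p = 0.092), with Cryab at 1.29 (SE 0.123) and Hsp90aa1 at -0.48 (SE 0.0534), and 4 higher and 9 lower without expressing replicate 1, and 2 and 5 with library totals. Interferon-stimulated genes numbered 11 higher and 4 lower of 26 (the same adjusted over the list alone; camera, adjusted p = 0.092), with Gbp3 at 1.19 (SE 0.0946), Tap1 at 1.14 (SE 0.0911), Oas1a at -2.08 (SE 0.181) and Ifitm1 at -1.37 (SE 0.0721).

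Cytosolic ribosomal protein genes fell. Of 67 tested members 56 fell and 0 rose in edgeR (59 and 0 adjusted over the list alone, and 0 rose at an unadjusted p under 0.05 and by DESeq2), with a median log2 fold change of -0.57 (camera, adjusted p = 2.8e-16, and adjusted p = 0.14 with an estimated correlation). Rps3 fell from 1354 ± 46.4 to 689 ± 11.9 CPM (SD, n = 3; -0.98, SE 0.0513), Rplp1 by 1.86 on the log2 scale (SE 0.103), Rps12 by 1.16 (SE 0.0648) and Rpl3 by 1.03 (SE 0.0633). These genes have many processed pseudogenes that can share their reads, and the values of individual members are uncertain. Together they took 1.26% ± 0.0963 of all counts in the expressing libraries and 0.859% ± 0.0110 in those labelled KO (SD, n = 3), a difference with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries can give (0.6 adjusted over 6 library measures).

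Among cell cycle and sterol genes, the called genes were mostly lower, by smaller amounts. Of 34 S phase and DNA replication genes 25 fell and 1 rose (26 and 1 adjusted over the list alone; median -0.31), with Pcna at -0.58 (SE 0.0637), Mcm2 at -0.52 (SE 0.0686), Ccne1, cyclin E1, at -0.68 (SE 0.0611) and Rrm1 at -0.47 (SE 0.0505). Of 34 G2 and M phase genes 14 fell and 0 rose (15 and 0 adjusted over the list alone; median -0.17), with Top2a at -0.48 (SE 0.0599) and Aurka at -0.49 (SE 0.0673). Of 25 cholesterol synthesis genes 17 fell and 0 rose (19 and 0 adjusted over the list alone; median -0.37), with Insig1 falling from 39.9 ± 1.87 to 27.1 ± 1.60 CPM (SD, n = 3; -0.56, SE 0.0745) and Lss, lanosterol synthase, at -0.47 (SE 0.0635). Camera gave adjusted p = 9.3e-07 for S phase, 0.0053 for G2 and M phase and 2.3e-04 for cholesterol synthesis, against adjusted p = 0.23, 0.25 and 0.14 with an estimated correlation. At an unadjusted p under 0.05 in edgeR, 1 gene of the G2 and M phase list and 0 of the cholesterol list were higher, and 0 of either by DESeq2. Without expressing replicate 1 the G2 and M phase list had 2 higher and 22 lower and the cholesterol list 1 and 19, with library totals 2 and 11 and 0 and 11, and with the GC trend removed the G2 and M phase list had 1 and 23. The cholesterol list had 0 higher and 11 lower without KO replicate 2 or KO replicate 3.

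In energy metabolism, 19 of 34 glycolysis and hypoxia genes fell and 7 rose (19 and 8 adjusted over the list alone; median -0.39). Ldha, lactate dehydrogenase A, fell from 1206 ± 100.4 to 605.1 ± 3.50 CPM (SD, n = 3; -0.995, SE 0.0652), Pfkp, a phosphofructokinase, fell (-1.20, SE 0.0539), and P4ha2, a collagen prolyl hydroxylase, rose by 1.1 (SE 0.0777). Of 49 nuclear genes for oxidative phosphorylation 18 fell and 0 rose (the same adjusted over the list alone; median -0.16; 1 higher at an unadjusted p under 0.05 in edgeR and 0 by DESeq2), with Atp5c1 at -0.47 (SE 0.0556). Camera gave adjusted p = 0.022 for glycolysis and 0.0076 for oxidative phosphorylation, and adjusted p = 0.41 with an estimated correlation for both; the glycolysis result was lost without expressing replicate 1 (0.051). Of 13 listed protein genes of the mitochondrial genome 7 were among the tested genes, and why the others were not was not examined. Of the 7 tested, 0 passed in edgeR in either direction, adjusted over all genes or over the list alone (camera, adjusted p = 0.75). At an unadjusted p under 0.05 in edgeR 1 was higher and 0 lower, as by DESeq2 and with library totals. With the GC trend removed or without a filter 1 was higher and 1 lower. These became 0 higher and 4 lower without expressing replicate 1 (median -0.16), and without expressing replicate 3 1 was higher and 0 lower. The oxidative phosphorylation counts became 5 higher and 19 lower without expressing replicate 1, 0 and 8 without expressing replicate 3, KO replicate 1 or KO replicate 2, 0 and 7 without KO replicate 3, 3 and 7 with library totals, and 2 and 26 with the GC trend removed.

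Signalling target lists divided between both directions. FGF and ERK targets numbered 7 higher and 6 lower of 19, with Spry4, a feedback inhibitor, at -1.35 (SE 0.0569) and Dusp5 at 0.80 (SE 0.0750), and 6 and 3 without KO replicate 1 or KO replicate 2, and 9 and 3 with library totals. WNT targets numbered 6 higher and 6 lower of 19, with the secreted inhibitors Dkk1 at 2.69 (SE 0.219) and Notum at -1.66 (SE 0.101). TGF-beta, NODAL and BMP targets numbered 6 higher and 8 lower of 18, with Msx2 at 1.31 (SE 0.114) and Id2 at -0.81 (SE 0.0725); their median was -0.10 and their mean 0.06. Adjusted over the list alone the counts were 7 and 6, 7 and 6, and 6 and 8. Camera gave adjusted p = 0.48, 0.76 and 0.81.

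In all, 15 of the 30 lists passed camera with the preset correlation, 6 higher and 9 lower, and 0 passed with an estimated correlation (6 at an unadjusted p under 0.05). By fry, which asks whether the members move one way on balance, 19 passed. These included lists that camera with the preset correlation did not pass: general factors, Mediator, SAGA and ATAC, heat shock (fry, adjusted p = 0.0019) and interferon-stimulated genes (0.00096). In the other 9 splits of the 6 libraries into 3 and 3, camera with the preset correlation passed 7 to 13 lists while edgeR called 0 genes (68 to 441 at an unadjusted p under 0.05). Each of those splits held libraries of both groups on both sides, so these counts do not show what chance alone gives.

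**Figure D3:**
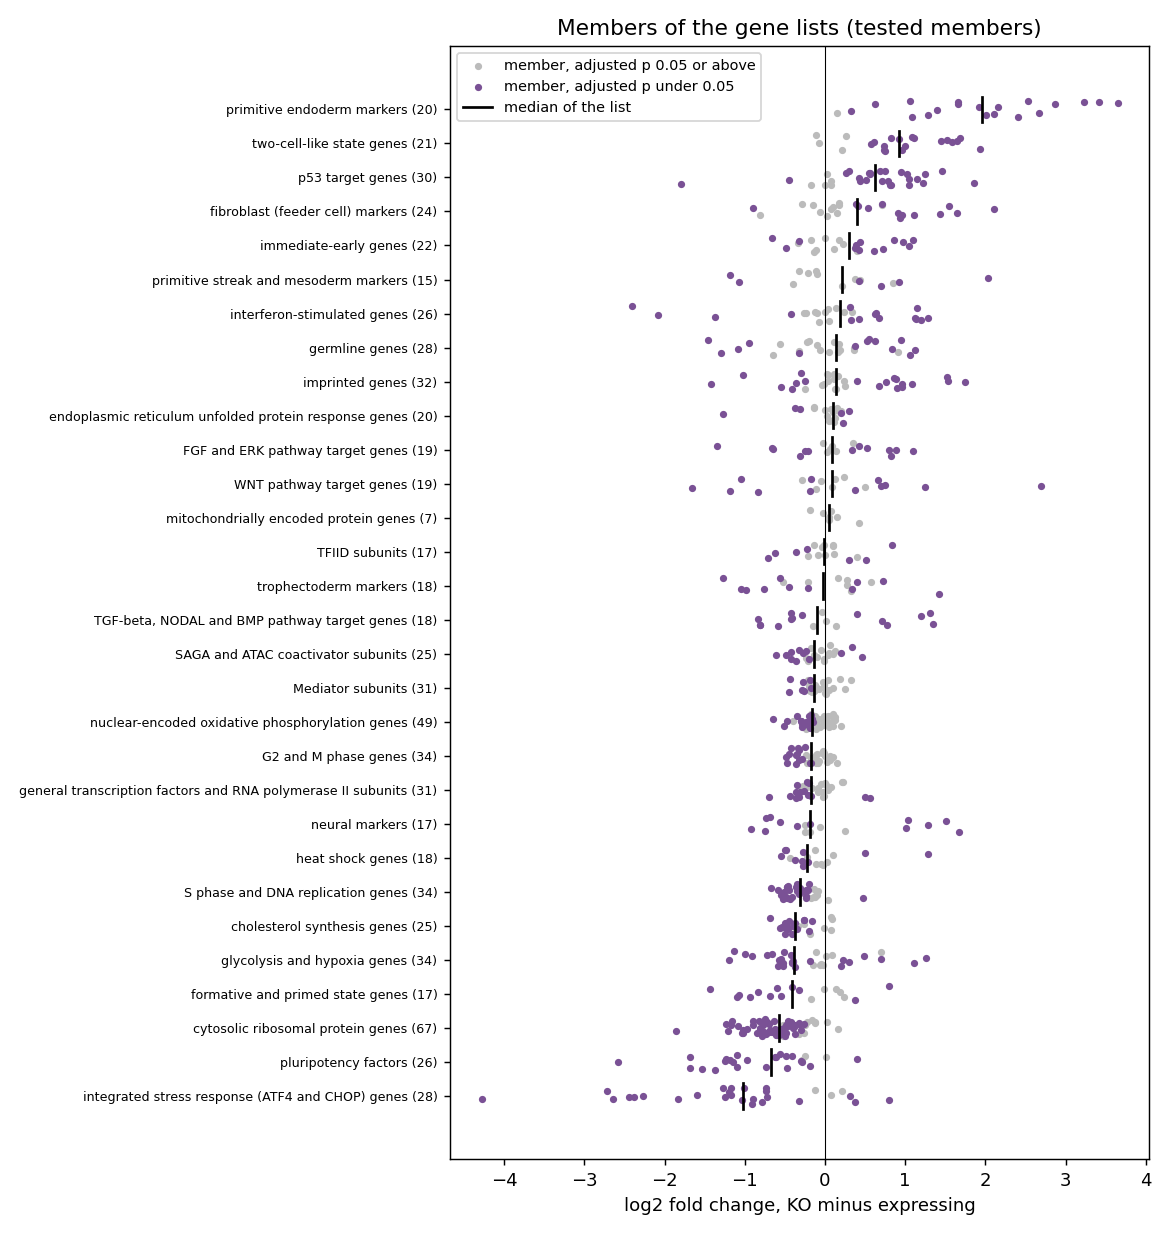
Log2 fold change (libraries labelled KO minus expressing libraries) of each tested member of the 30 gene lists, ordered by list median, with the number of tested members in brackets. Points are genes, in purple where they passed the test in edgeR, and black bars are list medians, from 1.96 for primitive endoderm markers to -1.02 for integrated stress response genes.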

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

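The GC trend removal, and leaving out libraries for the library measures, were chosen after seeing the data; the other alternatives were planned. Over the alternatives, summary counts of genes and lists stayed within 1.5 times their reported values except as follows. Requiring at least 1 CPM in 3 libraries gave 565 genes higher and 387 lower by 2-fold or more, from fewer genes tested (14226). An estimated correlation left 0 of 15 lists past camera, against 19 past fry. Leaving out each library in turn gave 2541 to 4851 genes higher, 2627 to 4589 lower, 807 to 1124 higher and 580 to 681 lower by 2-fold or more, 12225 to 13016 bounded within 2-fold, and 12 to 15 lists. Without expressing replicate 1, which stood apart in GC content, 4851 genes were higher and 4589 lower, and with the GC trend removed 4705 and 4747. Library totals without TMM gave 4466 higher and 2570 lower and moved the median of all genes to 0.08.

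The log2 fold change of Taf13 stayed above 0 in every alternative and passed the threshold with DESeq2 size factors (0.41, adjusted p = 0.0449, edgeR), library totals (0.49, 0.0197), no filter (0.40, 0.00257), the DESeq2 Wald test (0.41, 0.0216), the replicate block (0.41, 0.0241) and the GC trend removed (0.37, 0.00448). It did not pass with at least 1 CPM in 3 libraries (adjusted p = 0.0587, edgeR) or with predicted genes left out (0.0559). Leaving out each library in turn gave 0.28 to 0.57. Of these fits, those without expressing replicate 1 or 3 passed. Those without expressing replicate 2 (adjusted p = 0.1, edgeR), KO replicate 1 (0.0789), KO replicate 2 (0.166) or KO replicate 3 (0.15) did not. The cause was not tested.

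Reversals were limited to genes and lists that did not pass in the reported test. The log2 fold change of Tbp became 0.0093 and that of Taf11 0.047 with library totals. That of Taf3 became 0.0030 with DESeq2 size factors, 0.078 with library totals, 0.0033 by the DESeq2 Wald test, 2.5e-05 with predicted genes left out, and -0.049 to 0.0705 with each library left out in turn. That of Taf10 became 0.0096 with DESeq2 size factors, 0.083 with library totals, 0.0027 without a filter, 0.0029 with at least 1 CPM, 0.0086 by the DESeq2 Wald test, 0.0075 with the replicate block, 0.0070 with predicted genes left out, 0.046 with the GC trend removed, and -0.13 to 0.16 with each library left out in turn. Among lists, the camera direction turned for TFIID without KO replicate 2 (adjusted p = 0.97; 0.83 to 0.97 over the libraries left out) and for trophectoderm (0.96; 0.49 to 0.96) and mitochondrially encoded genes (0.25; 0.25 to 0.85) without expressing replicate 1, and the direction by fry differed for the unfolded protein response (0.59), WNT (0.45) and TGF-beta (0.26) lists. The cause was not tested.

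Among named genes other than Taf13, 12 of the recomputed calls were lost and 9 were gained, all for Taf1, Taf2, Taf4, Taf4b, Taf6, Taf9b, Tbp, Sox2 and Med16; the Sox2 call was also lost with the GC trend removed (adjusted p = 0.1, edgeR). Among lists, 31 were lost, 15 of them with an estimated correlation, and 6 were gained; a replicate block ended the calls of the immediate-early (camera, adjusted p = 0.062) and imprinted (0.064) lists. No pairing of the samples by replicate number was seen, though this check cannot exclude one. Same-numbered libraries deviated with correlations of 0.0236, -0.0342 and 0.0419 across genes, and 1 of 3 KO libraries correlated best with its own number. A replicate block gave 3243 genes higher and 3401 lower. In the simulation 77.6% of 2-fold changes were recovered, but only 200 genes were changed by known folds there, against 7117 called here. That share therefore does not estimate recovery in these data, though small changes can still be missed.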

Other observations

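The tests of Taf13, of partner genes and the splits of the libraries were chosen after the results were seen, as were the gene classes and the GC trend. In some gene classes outside the fixed lists, called genes lay mostly on one side. Of 70 small nucleolar RNA (snoRNA) genes tested 27 were lower and 0 higher in the libraries labelled KO (edgeR; 0 higher at an unadjusted p under 0.05 and 0 by DESeq2), with a median log2 fold change of -0.72 (camera, adjusted p = 5.3e-07, and adjusted p = 0.099 with an estimated correlation). With genes of at least 1 CPM 14 of 21 were lower, and with predicted genes left out 16 of 35. Of 17 genes listed as snoRNA hosts 10 were lower and 1 higher (median -0.73, camera, adjusted p = 6.3e-05, and adjusted p = 0.084 with an estimated correlation). That list holds the genes with numbered Snhg symbols, with Gas5, Zfas1 and Epb41l4aos added, and leaves out hosts with other symbols. It was written after the data were seen and the added genes all fell, so its camera result is descriptive only. Among hosts, Zfas1 fell from 77.3 ± 3.78 to 19.5 ± 0.477 CPM (SD, n = 3; log2 fold change -1.99, SE 0.0679), Snhg3 had -1.82, Snhg12 -1.15 and Gas5 -1.14. Many of these hosts carry a terminal oligopyrimidine start like that of ribosomal protein genes. Processed pseudogenes numbered 165 lower and 32 higher of 885 (median -0.36; 94 lower and 18 higher with at least 1 CPM, 108 and 42 with library totals, and 90 to 164 lower with a library left out), and may hold reads of the genes they copy, ribosomal protein genes among them. Leaving out genes by predicted-gene symbols kept 51 of them, 8 lower and 6 higher, so it does not test this. By camera, processed pseudogenes had adjusted p = 3.1e-05, and 0.05 (rounded) with an estimated correlation. snoRNAs carry no poly(A) tail, so their counts in poly(A) libraries may be host reads, which the table cannot separate.

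Long noncoding RNA genes antisense to, or sharing a promoter with, another gene were more often higher than lower in the libraries labelled KO: 177 of 511 were higher and 23 lower, with a median log2 fold change of 0.48. With genes of at least 1 CPM 115 were higher and 12 lower, and with predicted genes left out 36 and 6. By camera the antisense genes and the promoter-sharing genes each had adjusted p = 2.1e-07, and 0.05 with an estimated correlation. That last value is rounded and lies at the threshold. Over all tested genes, other classes showed an excess as well: processed transcripts numbered 97 higher and 24 lower (median 0.41), long intergenic noncoding RNA genes 139 and 67 (0.25), and genes annotated as not yet tested by experiment 81 and 16 (0.22). With predicted genes left out the first of these had 15 higher and 16 lower, the intergenic genes 24 and 29, and the last 6 and 0 of 16. The excess of the processed transcripts and intergenic genes was thus not seen there. Camera over all tested genes gave adjusted p = 3.8e-05, 0.0068 and 0.0047 for processed transcripts, intergenic genes and the last class. With an estimated correlation these were 0.05 (rounded), 0.23 and 0.46, so the intergenic genes and the last class did not pass. Whether the classes differ from one another was not tested. With genes of at least 1 CPM these classes had 63 and 23, 80 and 51, and 49 and 10, and the last had 48 to 82 higher and 8 to 37 lower with a library left out, and 95 and 29 with the GC trend removed. For the antisense and promoter-sharing genes, removing each library's GC trend left a median of 0.505, against that trend as the whole cause. The class median lay at percentile 100 of 10000 lists of protein-coding genes matched on abundance, GC content and length (their medians spanned -0.0044 to 0.137 in the central 95%). This argues against those properties as the whole cause, though how close the matches were was not checked. Opposite-strand partner reads that follow the partner's own counts cannot exceed the partner's fold. Over all 469 genes with a tested partner the median lay 0.506 above that of the partners with decreases set to 0 (95% bootstrap interval over genes, taken as independent, 0.428 to 0.562). The partners' median was -0.009, and 0 with decreases set to 0, so this gap is the median of the class genes itself. The partners did not rise as a set, which argues against such reads as the whole cause. Partner reads outside its exons are not covered by this comparison. The fold changes of genes and partners correlated (Spearman rho 0.226), so a contribution of partner reads stays open. Unspliced RNA or read-through past gene ends, which gene counts cannot show, and doxycycline stay open beside the loss of Taf13, so a response of these transcripts to that loss remains a hypothesis.

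Genes of the integrated stress response were lower in the libraries labelled KO, with a median log2 fold change of -1.02 (95% bootstrap interval over genes -1.26 to -0.74). That interval treats the genes as independent and leaves out the spread between dishes. Camera with an estimated correlation gave adjusted p = 0.14 for the list. With the GC trend removed 23 members were lower and 5 higher, with a median of -0.886. Without expressing replicate 1, the library that stood apart, 23 were lower and 4 higher, with a median of -0.919. The reported test gave 22 lower and 3 higher. Calls over all genes also rose from 7117, to 9452 and 9440 in these settings, so the counts alone say little. The fall of the list was somewhat smaller in both settings but remained, which argues against either as the whole cause. A different state of the medium or of cell density between dishes was not tested and may also move these genes. The loss of Taf13 is a candidate explanation that the design cannot separate from effects of doxycycline, which were not tested.

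Taf13 counts were not lower in the libraries labelled KO (log2 fold change 0.40, 95% interval 0.06 to 0.73). A mislabelled library is argued against, since 0 of 6 libraries correlated best with a library of the other group. An exchange of the labels of both groups as wholes cannot be told apart from the labels as given. The value set for it, after the data were seen, was a log2 fold change of at least 1 as labelled. It presumed that tagged and chromosomal transcripts were both counted, and the observed value was 0.395. A smaller rise would also go with an exchange if the tagged copy added few transcripts. The counts do not show which transcripts were counted, so the value cannot decide. Transcripts of an edited locus counted in both groups, with those of the tagged copy missed, would keep the interval between -1 and 1, and its upper bound was 0.726, which also goes with other explanations.

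Of the 10 splits of the 6 libraries into 3 and 3, only the labelled split (1 of 10) gave as many as 7117 changed genes, and the highest other gave 0. For changes of 2-fold or more the labelled split (1 of 10) gave 1575 and the highest other 0, and for lists past camera with the preset correlation it gave 15 (1 of 10) and the highest other 13. With 10 splits a share under 0.05 cannot be reached. Each other split also held libraries of both groups on both sides, so the difference between the groups entered the spread within each side. Gene calls were then unlikely from the start, and the other splits do not show what chance alone gives.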
